A study of Mus musculus with 27 samples.

How the data were processed

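RNA from mouse embryonic stem (ES) cells treated with small interfering RNAs (siRNAs) was measured on 27 Affymetrix mouse gene arrays. The values analysed were the log2 expression values the authors deposited, 1 per probeset and array, for 35556 probesets. Per the submitters' processing notes they were made with Affymetrix Expression Console and RMA, which corrects background, quantile-normalizes and summarizes probes. The versions of both tools and the genome build were not given in the sources used here. Array medians ranged from 6.22 to 7.96 and stepped between 6 sets of experiments. In PGK12.1 these were experiments 1 and 2 (4 arrays), experiment 3 (2 arrays), experiments A to C (7 arrays) and experiments D and E (6 arrays). The WD44 arrays (4) and the E14 arrays (4) formed a set each. The sets therefore appeared not to have been brought to 1 scale, and levels set across them carry that difference. No 2 arrays held identical values, and replicates of a group correlated at 0.981 to 0.996 across probesets. No read depth applies to arrays, and their number limits the precision.

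Probesets were named through the platform's annotation, with symbols updated by gene identifier through RefSeq genes of GRCm38.p6, which was used for names and chromosomes only. A single gene symbol was found for 21789 probesets, several for 1621 and none for 12146, and 21698 of the 21789 matched RefSeq. Probesets entered the tests with a mean log2 value of at least 6 and at least 1 symbol, which left 16283, of which 15287 had 1 symbol. Tests by chromosome and by gene list took 1 probeset per gene, the one with the highest mean, over 13989 genes (443 X-linked and 13503 autosomal).

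Arrays were grouped by the labels into 10 groups. All were fitted together with limma 3.58.1 in R 4.3.3, with a mean per group and a term for arrays given 2 rounds of RNAi, which left 16 residual degrees of freedom. Probesets were called at a Benjamini-Hochberg adjusted p under 0.05. The labels give each of the 12 experiments its own control array, so knockdown and control arrays are paired by experiment. A fit with the experiment as a block (9 residual degrees of freedom) was run beside it. Its value is given beside many results where it changed the call or moved a count by over 1.5 times, though not beside each. As a check of the pairing, deviations from the group means were correlated between arrays of an experiment. The correlation lay between -0.004 (MSL1, experiment B) and 0.867 (MOF, experiment 3), and was 0.011 in WD44 and 0.129 in E14. Correlation was higher with another experiment in MOF experiment 1 (0.678 against 0.667), MSL1 experiments A (0.467 against 0.456) and B (0.09), and NSL1 experiment E (0.628 against 0.501). With 2 experiments per group the own and other values are equal and opposite by construction. The check therefore did not settle the pairing, which was taken from the labels. The block also removes the steps between the 6 sets. The MSL1, NSL1 and double-target comparisons used 5 pooled control arrays from the 2 sets A to C and D to E, so that without the block the steps entered their fold changes. The steps also entered the spread per probeset that all comparisons share in the fit without the block.

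The shift of X-linked against autosomal genes was the difference of median log2 fold changes, tested two-sided by camera in limma with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 6 comparisons. Per experiment it was tested by an exact two-sided sign-flip test. The 22 gene lists (chromatin complexes, lineage and cell type markers, stress and metabolic pathways, X- and Y-linked genes) were tested the same way over 132 list and comparison pairs. Genes named in the text were the targeted genes, up to 10 higher and 10 lower genes with the largest fold change among those called with the same sign in every experiment, up to 5 X-linked genes each way, and up to 4 members with the smallest p from a list described. Groups, tests, lists and this rule were fixed before the data were examined.

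The procedures were tested on simulated data with 200 changed genes. At a true log2 change of -1, the fit without a block recovered 98% of genes for MOF in PGK12.1, 88% in WD44 and 96% in E14, over 16283 probesets. At -0.5 it recovered 54%, 40% and 34%, and with the block 84%, 88% and 94%. With no simulated effect, camera with the preset correlation called 53 of 220 list tests for MSL1, 42 of 220 for NSL1 and 56 of 220 for the double target in the fit without a block. For MOF in each line it called 1 of 220, and with the block at most 1 of 220 in any comparison. List calls in those 3 comparisons are therefore given with the block as well, and a call lost with it is not relied on. The simulated arrays were built from the experiment means and residual spread of the fit with the block, so that its model held by construction. Its higher recovery and low call rate there therefore cannot decide which fit suits the real arrays. Simulated genes varied independently around their experiment means. The simulated call rates therefore leave out correlation between list members, estimated at 0.037 for p53 targets and 0.49 for fibroblast markers.

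Alternatives covered the block as a fixed or random term, matched controls only, array weights, other filters, median centring, cyclic loess, a variance trend, a threshold of 1.5-fold, fry, and leaving out each array in turn. The normalization set as a block and fits within 1 set were chosen after seeing the data. For comparisons that share controls, unchanged groups were simulated 20 times.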

Results

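The arrays profiled undifferentiated mouse ES cells after RNAi against members of chromatin complexes that contain MOF (gene symbol Kat8), the acetyltransferase of histone H4 lysine 16. MSL1 is a scaffold of the MSL complex. The label NSL1 could stand for the NSL complex subunit now called Kansl1 or for the kinetochore gene Nsl1, and the labels do not say which. PGK12.1 is a female line from a 129 mother and a (129 x PGK)F1 father, and WD44 and E14 are male lines. In PGK12.1 there were 3 MOF arrays with 3 controls, and 3 MSL1, 3 NSL1 and 2 double-target (MOF and MSL1) arrays with 5 controls. WD44 and E14 had 2 MOF and 2 control arrays each. Cells received 100 pmol of siRNA for 48 h, which was a negative control siRNA in the control arrays. PGK12.1 experiments 1 and 2 had a second round of 400 pmol for 24 h, and double-target cells received 50 pmol of Msl1 siRNA besides. The labels describe separate RNAi treatments within a line. Limma p-values rest on 1 spread per probeset shared by all 27 arrays. Those of WD44 and E14, with 2 arrays per group, therefore draw mostly on the spread of PGK12.1 arrays.

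**Figure D1:**
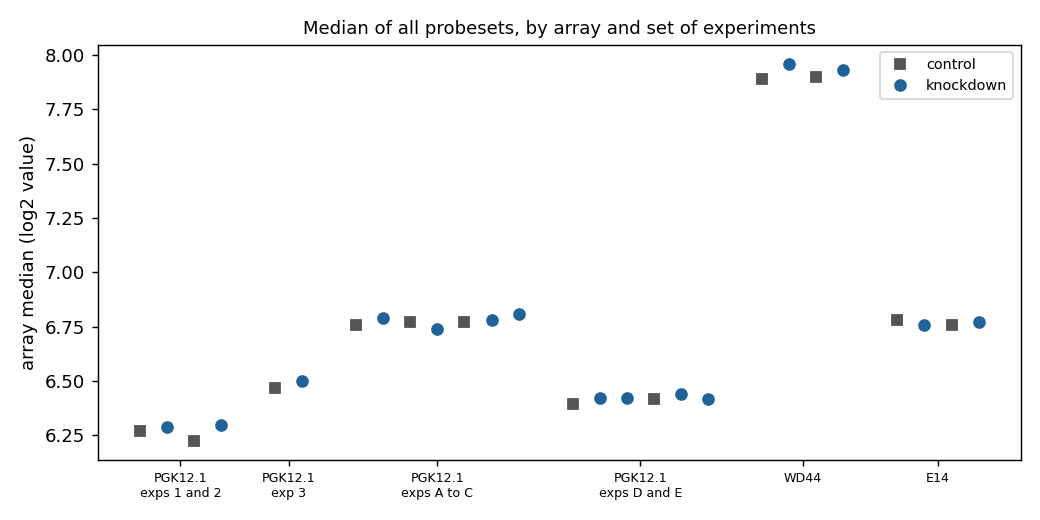
Median log2 value of all probesets for each of the 27 arrays (vertical axis), grouped by set of experiments (horizontal axis), with squares for control and circles for knockdown arrays. Medians lay between 6.225 and 6.3 in PGK12.1 experiments 1 and 2 and between 7.89 and 7.96 in WD44.

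The targeted transcripts were examined first. Kat8 (probeset 10557831) fell by 1.22 on the log2 scale in PGK12.1 (SE 0.07, 3 against 3 arrays, limma adjusted p = 6.65e-09), which left 38.7% to 48% of the control level in the 3 experiments. It fell by 0.84 in WD44 (SE 0.09, adjusted p = 0.00015) and by 0.68 in E14 (SE 0.09, adjusted p = 0.000925). Msl1 (probeset 10381018) fell by 1.00 after MSL1 siRNA (SE 0.06, adjusted p = 3.68e-08), with 42.9% to 56.3% left. In double-target cells Kat8 fell by 0.93 (SE 0.07, adjusted p = 9.73e-07) and Msl1 by 0.41 (SE 0.07, adjusted p = 0.00433). In arrays labelled NSL1 the probesets of Kansl1 disagreed. One (10391990) fell by 0.27 (SE 0.05, adjusted p = 0.000331), and the other (10392010) stood at 0.35 (SE 0.17, adjusted p = 0.14), or 0.50 with the experiment as a block (adjusted p = 0.00648). Nsl1 stood at 0.06 (SE 0.08, adjusted p = 0.635). By experiment, 10391990 lay between -0.31 and -0.11 in these arrays and Nsl1 between 0.09 and 0.27. The rise of 10392010 was not particular to them. It also lay between 0.06 and 0.78 after MOF siRNA in PGK12.1, at 0.86 and 0.63 in WD44 and at 0.42 and 0.48 in double-target cells. In E14 it stood at -0.10 and 0.17. Because the probesets disagree, these arrays are called arrays labelled NSL1, or NSL1 for short, and the name stands for the label only.

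**Figure D2:**
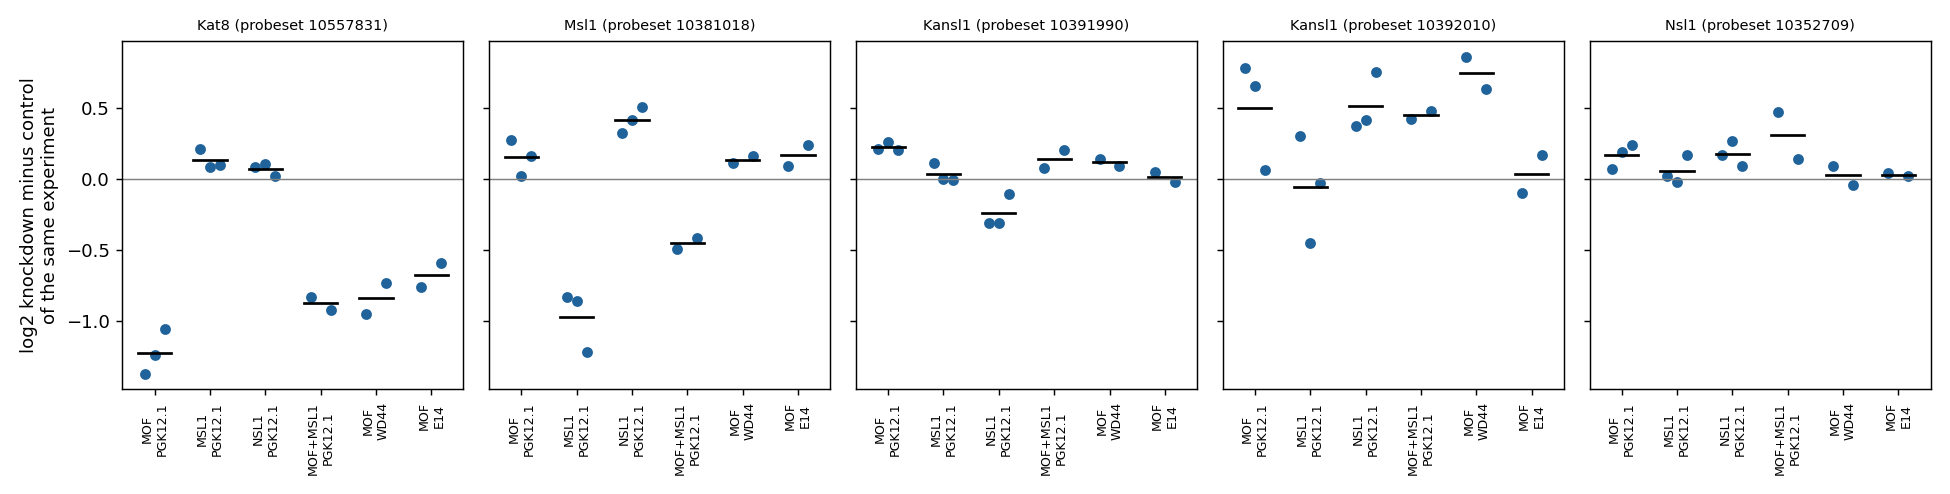
Log2 knockdown minus control of the same experiment (vertical axis) for the targeted genes, 1 panel per probeset, by comparison (horizontal axis). Points are experiments and lines are means. Kat8 lay between -1.37 and -1.06 in the MOF experiments of PGK12.1, whereas the probesets of Kansl1 moved apart in arrays labelled NSL1. Kansl1 probeset 10392010 also lay above 0 in the MOF experiments of PGK12.1 and WD44.

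MOF knockdown in PGK12.1 raised p53 target genes. Of 19 measured p53 targets, 16 rose, none fell and 3 did not pass the test (17 rose when adjusted over the list alone). Trp53inp1, a p53-induced nuclear protein, rose by 0.68 (SE 0.06, adjusted p = 1.79e-06), Btg2, an antiproliferative factor, by 0.59 (SE 0.06), Plk2, a polo-like kinase, by 0.71 (SE 0.08) and the cyclin gene Ccng1 by 0.41 (SE 0.05). The list median was 0.41 (adjusted camera p = 7.92e-23, and adjusted p = 2.44e-05 with an estimated correlation), and the median was 0.34 to 0.48 in the 3 experiments. Dglucy, which encodes a mitochondrial D-glutamate cyclase, rose most, by 1.29 (SE 0.11, adjusted p = 1.79e-06). Ahnak2 rose by 1.07, the anoctamin Ano3 by 1.03, Ttll6, a tubulin polyglutamylase, by 1.01, Ephx2, the soluble epoxide hydrolase, by 0.85, and Dnah8, an axonemal dynein, by 0.68. Ptpn14, a tyrosine phosphatase, rose by 0.67, as did Ddit4, a stress-induced inhibitor of mTORC1 signalling, by 0.66. After Kat8, the largest falls were in Ttc26, an intraflagellar transport gene (-1.03, SE 0.13, adjusted p = 7.64e-05), and Ssh2, a cofilin phosphatase (-0.97, SE 0.21). Zfp72 (-0.93), Lipa, the lysosomal acid lipase (-0.88), As3mt, an arsenic methyltransferase (-0.88), and Gstm5, a glutathione transferase (-0.87), also fell. So did Tbc1d7, a subunit of the TSC complex (-0.87), and Myd88, the adaptor of Toll-like receptors (-0.86).

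Other lists moved in single members after MOF knockdown in PGK12.1. Of 9 NSL complex genes 3 rose, among them Kansl2 (0.28) and Ogt (0.21), and Kat8 fell, while of 4 MSL complex genes Kat8 and Msl3 (-0.27) fell. Of 18 cholesterol synthesis genes 3 fell, namely Nsdhl (-0.46), Hsd17b7 (-0.22) and Dhcr7 (-0.26). Among 20 lysosome and autophagy genes Lamp2 (0.52) and Ctsd (0.32) rose and Ctsz (-0.49) fell, and among 21 genes of the ATF4 and unfolded protein response Sesn2 (0.35), Ddit3 (0.27) and Atf3 (0.31) rose. Of 27 naive pluripotency genes, Tdgf1 alone passed the test (-0.17, adjusted p = 0.0445, and 0 when adjusted over the list alone), and Nanog stood at -0.14 (adjusted p = 0.131, or 0.0427 with the block). With the block 3 naive pluripotency genes were lower and 1 was higher, and 5 lysosome and autophagy genes were higher and 3 lower. By camera none of the 21 lists other than the p53 targets was called as a whole in this comparison. By fry, which does not set a list against other genes, the MSL complex, which holds Kat8 itself, was called besides (adjusted p = 2.45e-06). Fry with the block also called trophectoderm (0.00284), mesoderm (0.0149), two-cell-like (0.015) and mitosis genes (0.0252). In all, 1250 probesets changed, 438 higher and 812 lower, and 104 of them by at least 1.5-fold. With the experiment as a block 3816 changed, all 1250 among them in the same direction, and cyclic loess gave 720 higher and 1275 lower. Centring each array on its median, which moves all its probesets alike, gave 795 higher and 691 lower. With 1 array left out the count ran from 437 (without either array of experiment 3) to 904 (without control 1).

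Whether X-linked genes respond apart from autosomal genes is the question that MOF raises, since its fly counterpart acts in X dosage compensation. After MOF knockdown in PGK12.1, the median log2 change of X-linked genes lay 0.05 under that of autosomal genes (difference -0.05, adjusted p = 0.01 by camera in limma). Among 443 X-linked genes 51 fell and 11 rose, or 11.5% against 5.2% of autosomal genes lower and 2.5% against 2.9% higher. With the block 119 fell and 31 rose, or 26.9% against 14.3% lower and 7% against 9.9% higher. Atg4a, an autophagy protease, fell by 0.94 (SE 0.09, adjusted p = 4.78e-06), Zfp280c by 0.85, the kinase Stk26 by 0.83, Car5b, a mitochondrial carbonic anhydrase, by 0.81, and Mospd1 by 0.72. Gria3, an AMPA receptor subunit, rose by 0.61, as did the lysosomal membrane gene Lamp2 (0.52), Renbp (0.45), the homeobox gene Rhox9 (0.39) and Fam120c (0.36). The shift was -0.087 among genes of low mean level (adjusted p = 5.89e-05, and with an estimated correlation p = 0.319 without and 0.000591 with the block) and -0.11 among those of middle level (adjusted p = 0.000864, and p = 0.379 and 0.0314). Among highly expressed genes it was -0.0033 (adjusted p = 0.603). It was lost with an estimated correlation (adjusted p = 0.938 without and 0.0682 with the block). Without a filter on low values it was -0.03 (adjusted p = 0.156), and without the control or the knockdown array of experiment 3 it was -0.045 (adjusted p = 0.0793 either way).

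**Figure D3:**
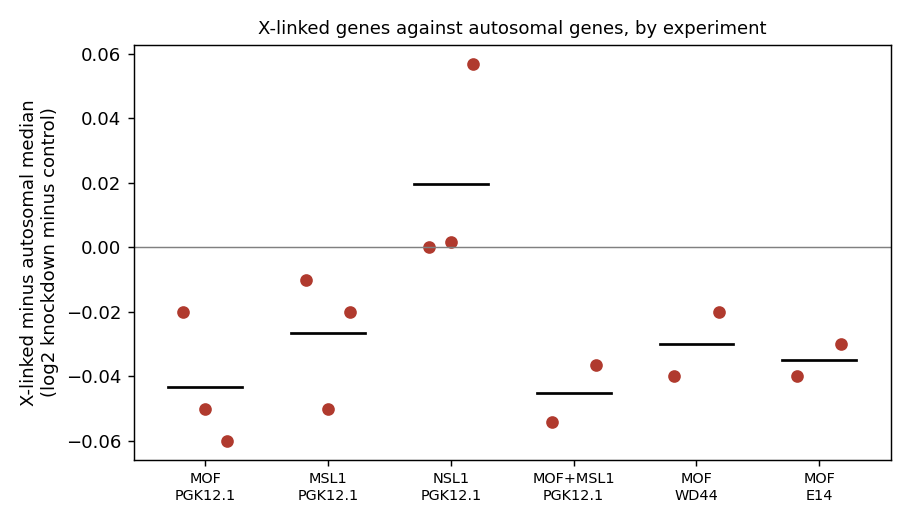
Median log2 change of X-linked genes minus that of autosomal genes (vertical axis) by comparison (horizontal axis). Points are experiments, knockdown minus control, and lines are means. All 7 experiments with MOF siRNA alone lay between -0.06 and -0.02, and the 3 experiments labelled NSL1 between 0 and 0.057.

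MSL1 knockdown in PGK12.1 changed 10 probesets. Besides Msl1 itself, Firre, an X-linked long noncoding RNA, fell by 0.52 (SE 0.08, adjusted p = 0.0159), Dnajc6, which encodes auxilin of clathrin uncoating, by 0.43 (SE 0.06) and Myof, encoding myoferlin, by 0.32 (SE 0.05). Higher were Cep170b (0.45), Ltbp4, a latent TGF-beta binding protein (0.45), Crip2, a LIM domain protein (0.43), the HMG-box factor Sox15 (0.42), Rtkn (0.38) and Tgm1, a transglutaminase (0.35). With the block 30 probesets changed, 16 higher and 14 lower, including all 10. With array weights 1221 did (464 higher, 757 lower). Without the MSL1 array of experiment B, Msl1 alone was called. With matched controls only, limma called 0, against 1193 at an unadjusted p under 0.05. Of the 19 p53 targets none passed over all probesets and 2 rose when adjusted over the list alone. Camera did not call the list (median 0.076, adjusted p = 0.483), whereas fry did (adjusted p = 0.0394, or 0.0169 with the block), as did camera with the block (median 0.069, adjusted p = 0.00594), but not with the block and an estimated correlation (adjusted p = 0.148). The calls of naive pluripotency, cholesterol synthesis, glycolysis, replication, oxidative phosphorylation and two-cell-like genes in the fit without a block were all lost with it, where the smallest adjusted p was 0.102. X-linked genes stood at -0.033 against autosomal genes (adjusted p = 0.0828) and at -0.025 with the block (adjusted p = 0.00185, and 0.0682 with an estimated correlation), and all 3 experiments were below 0.

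In arrays labelled NSL1, p53 targets were again higher. Of 19 p53 targets 17 rose (17 when adjusted over the list alone), led by Plk2 (1.21, SE 0.07, adjusted p = 1.62e-09), Btg2 (0.82, SE 0.05), Pidd1, a death-domain protein (0.82, SE 0.08), and Sesn2, a stress-induced sestrin (0.48, SE 0.06). The list median was 0.40 with the block (adjusted p = 1.5e-09, and 0.00803 with an estimated correlation) and 0.39 without it (adjusted p = 2.36e-13, and 0.000275). Of 18 cholesterol synthesis genes 9 fell, among them Pmvk (-0.72), Lss (-0.59), Nsdhl (-0.46) and Hsd17b7 (-0.33), and none rose (9 lower and 1 higher when adjusted over the list alone), though camera did not call the list (adjusted p = 0.116 with and 0.107 without the block). Fry called it (adjusted p = 2.05e-06). Of 42 nuclear genes of oxidative phosphorylation 7 fell (5 when adjusted over the list alone) and 11 with the block, including the complex I subunits Ndufa9 (-0.59) and Ndufv1 (-0.50), and Sdhb of complex II (-0.32). Camera did not call that list without the block (adjusted p = 0.396), called it with the block (adjusted p = 0.0474) and did not with an estimated correlation besides (adjusted p = 0.838). Of 20 glycolysis and hypoxia genes 6 fell, among them Egln1 (-0.36) and Hk2 (-0.28), and 6 did when adjusted over the list alone, but camera did not call the list (adjusted p = 0.481, or 0.236 with the block). Msl1 rose by 0.47 and Msl2 by 0.25, whereas Msl3 fell by 0.46.

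The largest rises in arrays labelled NSL1 were in Ccdc141 (1.65, or 1.34 with the block), Ano3 (1.57), Gpnmb, a melanosomal glycoprotein (1.40), Ms4a10 (1.34) and Lcp1, the actin-bundling L-plastin (1.33). Next came the neuronal transcription factor Neurod1 (1.25), Aox3, an aldehyde oxidase (1.24), Btla (1.19) and Cspg4b (1.17). Arpin, an inhibitor of the Arp2/3 complex, fell by 1.55 (SE 0.17, adjusted p = 9.71e-07), Tbc1d7 by 1.49, Plgrkt, a plasminogen receptor, by 1.45 and Pcbd1, an enzyme of tetrahydrobiopterin recycling, by 1.44. Plekhb1 (-1.39), Siae, a sialic acid acetylesterase (-1.36), Cyp4f16 (-1.32) and Ttc26 (-1.28) also fell. X-linked genes went both ways, with falls in Zc4h2 (-1.42), Atg4a (-1.32), Rpgr, a ciliary protein (-1.13), Cd99l2 (-1.09) and Mtmr1 (-1.07) and rises in Ripply1 (1.00), Gria3 (0.91), Gpr50 (0.84), Nexmif (0.72) and Nap1l2 (0.70). Of the 443 X-linked genes 92 fell and 53 rose, against 2582 and 1466 of 13503 autosomal genes, and 116 and 98 with the block. Their shift was 0.025 (adjusted p = 0.89). In all, 4603 probesets changed, 1750 higher and 2853 lower, and 802 by at least 1.5-fold. With the block 6480 changed (2999 higher and 3481 lower), 4420 of them shared in direction, and within experiments D and E alone 5262 did (2366 higher and 2896 lower). Median centring gave 2854 higher and 2242 lower, and matched controls only 1089. Without the NSL1 array of experiment C 7325 were called, and without that of experiment E 3084.

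Double-target knockdown of MOF and MSL1 in PGK12.1 also raised p53 targets. Of 19, 10 rose (11 when adjusted over the list alone), led by Plk2 (0.77, SE 0.09), Sesn2 (0.50), Pidd1 (0.59) and Btg2 (0.38). The list median was 0.21 (adjusted p = 1.24e-13) and 0.27 with the block (adjusted p = 9.47e-12, and 0.00528 with an estimated correlation). Pou2f3, a POU-domain factor, rose by 1.09 (0.94 with the block), the histone gene H2bc4 by 1.06 (0.72), Gpx2, a glutathione peroxidase, by 0.95 (0.46), Neurod1 by 0.94 (0.66) and Ephx2 by 0.88 (0.65). Got1l1 (0.92, or 0.36 with the block), Ceacam10 (0.86, 0.42), Them5 (0.80, 0.63), Fbp2 (0.78, 0.35) and Liph (0.78, 0.62) followed. Lower were Acot2, a mitochondrial thioesterase (-1.09, or -0.50 with the block), Aldh3b1 (-1.05, -0.36), Arpin (-1.01, -0.68), Ucma (-0.99, -0.68), Ehd3 (-0.99, -0.38), Ica1 (-0.98, -0.38), Hopx (-0.92, -0.29) and Clip3 (-0.90, -0.65). The median of all probesets was -0.10 in this comparison without the block, since its arrays came from experiments D and E and its controls from A to E.

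Of the 1612 probesets changed after double-target knockdown, 438 were higher and 1174 lower. With the block there were 1048 (528 higher, 520 lower), of which 670 were shared in direction, and with matched controls only 44. Leaving out 1 array gave 89 (without knockdown E) to 5100 (without control D). Median centring gave 847 higher and 945 lower. Of 4 MSL complex genes the targets Kat8 and Msl1 fell, and the list was called with the block (adjusted p = 0.0115), though not with an estimated correlation besides (adjusted p = 0.212). Calls of naive pluripotency, ATF4 response, replication, mitosis, oxidative phosphorylation and two-cell-like genes were lost with the block, where the smallest adjusted p was 0.102. X-linked genes shifted by -0.072 (adjusted p = 0.01) and by -0.054 with the block (adjusted p = 0.00166, and 0.0682 with an estimated correlation). The shift was -0.13 among genes of middle level (adjusted p = 0.00051, and with an estimated correlation p = 0.354 without and 0.0299 with the block) and -0.069 among highly expressed genes (adjusted p = 0.000135, and p = 0.142 and 0.111). Among genes of low level it was -0.03 (adjusted p = 0.603), or -0.052 with the block (adjusted p = 0.036). Falls were largest in Stk26 (-0.91, or -0.46 with the block), Sh3bgrl (-0.82, -0.36), Map7d2 (-0.80, -0.31), Arxes1 (-0.78, -0.59) and Usp51 (-0.78, -0.46). Wdr45 rose by 0.18, and Ccdc160 (0.36), Ripply1 (0.33), Morf4l2 (0.23) and Zfx (0.18) rose without the block but not with it (adjusted p = 0.0548, 0.0596, 0.13 and 0.14).

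In male WD44 cells MOF knockdown lowered the small nucleolar RNA gene Snord118 by 1.52 (SE 0.21, adjusted p = 0.00176), Capsl by 0.89, Ttc26 by 0.82 and Tbc1d7 by 0.81. Crygd (-0.80), Bin2 (-0.80), Stox2 (-0.78), Lefty2, a Nodal antagonist (-0.74), and Snord35a (-0.71) also fell. Serpinb9b rose by 0.79 (SE 0.15, adjusted p = 0.0168), Snord85 by 0.76, the matricellular gene Ccn1 by 0.51, Tmbim4 by 0.47 and Krt18, an epithelial keratin, by 0.45. Hs6st3, Jam2, Cald1, Fxyd6 and Epha4 rose by 0.34 to 0.37. Among X-linked genes Cetn2, a centrin (-0.49), Ocrl (-0.48), Zc4h2 (-0.47) and Fundc1 (-0.37) fell, and Wdr45 rose (0.30). With the block 62 X-linked genes fell and 19 rose, or 14% against 8.1% of autosomal genes lower and 4.3% against 4.4% higher. X-linked genes together stood at -0.03 against autosomal genes (adjusted p = 0.289 by camera in limma). Those of low mean level stood at -0.057 against autosomal genes of that level (adjusted p = 0.011 by camera in limma, and with an estimated correlation p = 0.522 without and 0.0114 with the block). The X-linked genes themselves had a median log2 change of -0.05 together and 0.0175 at low level. In all 99 probesets changed, 14 higher and 85 lower, against 2013 with the block (714 and 1299) and 62 higher and 42 lower after median centring. Without the knockdown array of experiment 1, only 1 was called, and without that of experiment 2, 46.

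Several lists moved together in WD44 with few members past the test singly. Primed epiblast genes had a median of -0.28 (adjusted p = 0.00256), with 0 of 11 past the test over all probesets 5 lower when adjusted over the list alone and 6 lower with the block, and Lef1 at -0.55, Pou3f1 at -0.40 and Fgf5 at -0.40. Trophectoderm genes had a median of 0.19 (adjusted p = 0.00256), and of 12 Krt18 rose (2 when adjusted over the list alone, 3 with the block). Endoderm genes stood at 0.14 (adjusted p = 0.00496, 0 of 18, or 2 higher when adjusted over the list alone, and 4 higher and 1 lower with the block), with Sparc at 0.28 and Col4a2 at 0.42. Fibroblast markers, which feeder cells express, stood at 0.23 (adjusted p = 0.000704, 0 of 18 in either adjustment, but 8 higher with the block), with Acta2 at 0.97 and Col1a1 at 0.38. Lysosome and autophagy genes stood at 0.08 (adjusted p = 0.00809, 0 of 20, or 4 higher when adjusted over the list alone, and with the block 4 higher and 1 lower with the list no longer called, adjusted p = 0.117). Glycolysis and hypoxia genes stood at -0.15 (adjusted p = 0.00752, 0 of 20, or 1 lower when adjusted over the list alone, and 4 with the block) and replication genes at -0.085 (adjusted p = 0.00623, 0 of 39 in either adjustment, but 7 lower with the block). Genes of oxidative phosphorylation stood at -0.078 (adjusted p = 0.0448), where Ndufs7 fell by 0.27 and 3 genes fell with the block (adjusted p of the list 0.117). The p53 targets stood at 0.08 (adjusted p = 0.00125, 0 of 19, or 2 higher when adjusted over the list alone, and 3 with the block). Every one of these calls was lost with an estimated correlation, where the adjusted p was 0.158 for primed epiblast and trophectoderm, 0.0988 for p53 targets and between 0.593 and 0.769 for the others. With the block and an estimated correlation, endoderm genes alone of these lists passed (adjusted p = 0.0494).

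In male E14 cells MOF knockdown raised Sfn, which encodes 14-3-3 sigma, by 0.94 (SE 0.15, adjusted p = 0.00569), Cpne5 by 0.73, Lfng, a modifier of Notch receptors, by 0.72 and Ifi30, a lysosomal thiol reductase, by 0.70. Pagr1a (0.69), Sox15 (0.64), Crip1 (0.64), Tapbp, tapasin of antigen loading (0.62), Ldhb (0.61) and the X-linked Renbp (0.60) also rose. Anpep, aminopeptidase N, fell by 1.00 (SE 0.10, adjusted p = 0.000106), Eid1 by 0.91, Dennd4a by 0.67, Slc38a9, a lysosomal amino acid transporter, by 0.65 and the X-linked Zc4h2 by 0.64. Tmem68 (-0.58), the helicase gene Wrn (-0.58), Pigk (-0.57) and the X-linked Map7d3 (-0.57), Atg4a (-0.55) and Fundc1 (-0.29) fell as well, and the X-linked Eda2r (0.40) and Wdr45 (0.34) rose. Of 19 p53 targets 4 rose (8 when adjusted over the list alone, and 8 with the block), namely Btg2 (0.40), Eda2r, Trp53inp1 (0.36) and Aen (0.35), with a list median of 0.22 (adjusted p = 9.55e-09, and 0.00233 with an estimated correlation). Replication genes stood at 0.075 (adjusted p = 0.00636, or 0.623 with an estimated correlation) and genes of oxidative phosphorylation at 0.053 (adjusted p = 0.0315, or 0.769), with none past the test in either list. With the block 2 replication genes rose, and of oxidative phosphorylation 2 rose and 2 fell (adjusted p of the list 0.136). X-linked genes together stood at -0.035 against autosomal genes (adjusted p = 0.178 by camera in limma). In all 109 probesets changed (44 higher, 65 lower), and 1357 with the block (586 and 771). Limma with matched controls only called 0, against 3484 at an unadjusted p under 0.05, and median centring gave 74 higher and 85 lower. Without the knockdown array of experiment 2, 6 were called, and without its control 173.

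**Figure D4:**
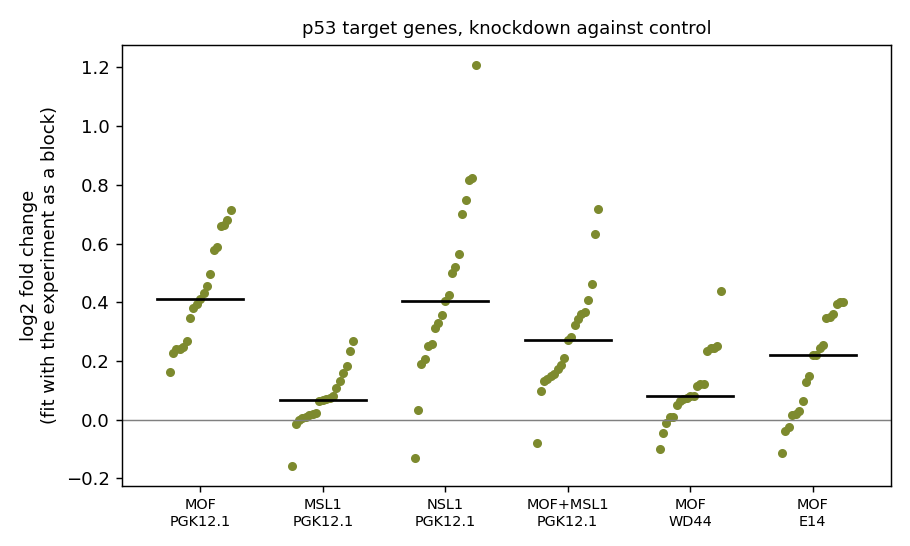
Log2 fold change of the 19 measured p53 target genes (points, vertical axis) by comparison (horizontal axis), from the fit with the experiment as a block, with the median as a line. The median was 0.41 after MOF knockdown in PGK12.1, 0.08 in WD44 and 0.22 in E14.

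The lists of mesoderm, neural ectoderm, interferon response, germline, X inactivation centre and Y-linked genes were called by camera in no comparison, and the smallest adjusted p among them was 0.107 (germline genes in E14). Fry called interferon genes in arrays labelled NSL1 (adjusted p = 0.0404, or 0.00117 with the block) and Y-linked genes after double-target knockdown (adjusted p = 0.0299). The Y-linked call, on 2 measured genes in a female line, was lost with the block (fry adjusted p = 0.0612) and is not relied on. With the block fry also called germline (0.0115) and mesoderm genes (0.015) in WD44 and interferon genes in E14 (0.0479). Across the 7 experiments with MOF siRNA alone in the 3 lines, the p53 list median was above 0 in all 7 (mean 0.26 ± 0.17, SD) and the X-linked minus autosomal median below 0 in all 7 (mean -0.037 ± 0.015, SD). Either gave an exact two-sided sign-flip p = 0.0156, the smallest that 7 experiments allow. With X set against chromosomes 1 to 19, the X had the lowest median of 20 in the MOF comparisons of all 3 lines and in the double-target comparison. Over 20 chromosomes, camera called the X in the last (adjusted p = 0.0273) and, with the block, in MOF (0.0125), MSL1 (0.0185) and the double target (0.00552) in PGK12.1. Autosomes were called too, namely chromosome 8 in the double target (median 0.079 above the rest, adjusted p = 0.0273) and in MSL1 (-0.052, adjusted p = 0.0233), chromosome 13 in MSL1 without and with the block (adjusted p = 0.0233 and 0.0368), and chromosome 7 in MSL1 with it (0.0492). Both calls of chromosome 8 were lost with the block, where its median was -0.0044 in the double target (adjusted p = 0.867) and 0.0069 in MSL1 (adjusted p = 0.589). With an estimated correlation the unadjusted p of the X was 0.482 for the double target without the block, and with it 0.0298 (MOF), 0.0341 (MSL1) and 0.0228 (double target). The first of these cannot decide, since that test called 0 of 10 simulated runs at a true shift of -0.1. Shifts of the X did not pass a test of difference between lines (adjusted p = 0.118 for either male line against PGK12.1).

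Fold changes were compared across genes, which are not independent replicates, over 15 pairs of comparisons. MOF in PGK12.1 and arrays labelled NSL1, which shared no controls, correlated at 0.563, with 577 probesets lower in both (142.3 from independent lists) and 287 higher in both (47.1), and with the block 1416 (485.5) and 861 (284.6). MOF in PGK12.1 correlated at 0.509 with WD44 and at 0.473 with E14. Where controls were shared, simulated unchanged groups already correlated at 0.326 to 0.372. Arrays labelled NSL1 and double-target arrays correlated at 0.559 (covariance 0.035, simulated 0.00423) and at 0.377 and 0.535 with separate controls. MSL1 and double-target fold changes correlated at -0.489 without the block, where the steps between sets enter. They correlated at 0.342 with the block, where 10 probesets were higher in both (0.5 from independent lists) and 6 lower in both (0.4), and at 0.186 with separate controls.

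Control arrays of female PGK12.1 were set against those of the male lines as a check of the labels, with levels taken across separately normalized sets. X-linked genes stood 0.53 above autosomal genes in female minus male arrays (camera p = 0.0102 with an estimated correlation). Uty, a Y-linked demethylase gene, had a mean log2 value of 9.54 in WD44 and 8.60 in E14 controls (2 arrays each), against 3.76 ± 0.36 (SD, n = 5) and 3.52 ± 0.68 (SD, n = 3) in PGK12.1 controls. Some other Y-linked genes did not part E14 from PGK12.1. Kdm5d stood at 8.22 in WD44 and 4.29 in E14, against 4.53 and 4.42 in the PGK12.1 control groups, and Sry at 8.53 and 7.04, against 7.42 and 6.77. Xist, the RNA of X inactivation, stood at 5.52 ± 0.21 (SD, n = 5) and 5.67 ± 0.70 (SD, n = 3) in PGK12.1, 6.67 in WD44 and 5.85 in E14 controls.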

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

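The tests of the explanations below were all chosen after the results were seen, whereas the other splits of the arrays were set before.

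The MOF effect differed between cell lines by tests of the difference itself in limma. In WD44 minus PGK12.1 16 probesets differed, in E14 minus PGK12.1 11 and in E14 minus WD44 5. With the block these counts were 360, 407 and 226, and with 1 array left out they ran from 0 to 14, 0 to 24 and 2 to 24. The median change of p53 targets was lower in WD44 than in PGK12.1 (difference -0.32, adjusted p = 2.75e-16, and p = 2.96e-06 with an estimated correlation) and in E14 than in PGK12.1 (difference -0.21, adjusted p = 9.87e-10, and p = 8.75e-05). It was 0.12 larger in E14 than in WD44 (adjusted p = 0.0239), a call that ended with an estimated correlation (p = 0.0755) and with the block (p = 0.0536). Kat8 also fell less in the male lines, and line, sex, genetic background and set of arrays differ together. In PGK12.1 experiment 3, given 1 round of 100 pmol as in the male lines, the p53 median was 0.45, against 0.10 and 0.07 in WD44 and 0.25 and 0.15 in E14.

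Single genes differed between lines as well. In WD44 minus PGK12.1, Slc38a5 (0.83), Tmbim4 (0.67) and Nsdhl (0.62) were higher, and Snord118 (-1.85), Dglucy (-1.22), Snord35a (-1.02), Ttll6 (-0.74) and Gk5 (-0.69) lower. In E14 minus PGK12.1, H2-Q4 (0.75), Btrc (0.51) and Clmn (0.49) were higher, and Dglucy (-1.02), Kbtbd11 (-0.85), Ccn1 (-0.70), Myof (-0.69) and Nptx1 (-0.64) lower. In E14 minus WD44, Cpne5 was higher (0.69), and Myof (-0.87), Mme (-0.79), Ccn1 (-0.76) and Cald1 (-0.71) were lower.

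Probesets without a gene name, which no comparison of the report used, also changed. Of 6302 above the filter, 81 changed after MOF knockdown in PGK12.1, 499 in arrays labelled NSL1 and 7 after double-target knockdown, and with the block 252, 650 and 0. In WD44 0 changed without the block and 8 with it.

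The p53 targets rose in PGK12.1 after MOF knockdown and in arrays labelled NSL1. Transfection of siRNA is part of both sides of each comparison, since control cells received a negative control siRNA. As the whole cause it is also argued against by the MSL1 arrays. The median over p53 targets of the difference per gene, NSL1 minus MSL1, was 0.29 (camera p = 0.000404, with the block and an estimated correlation). An effect of the MOF siRNA alone is argued against by the rise with NSL1 siRNA (camera p = 0.000182 with the block and an estimated correlation). Separate scales are argued against by the list medians within an experiment, the lowest of which was 0.34 over the 6 MOF and NSL1 experiments in PGK12.1. Off-target effects of both siRNAs and a response to loss of the targeted factors stay open and were not tested, and in arrays labelled NSL1 the probesets of Kansl1 disagreed on such a loss.

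X-linked genes were lower after MOF knockdown, by a small amount. Their median of -0.041 over 7 experiments lay below the lowest of 10000 autosomal sets matched on level (-0.031), most of which lay between -0.016 and 0.011, which argues against expression level. Values in the 3 experiments labelled NSL1 were all higher (difference 0.057, exact two-sided permutation p = 0.00833, the smallest that 3 against 7 experiments allow). This argues against a general response to a knockdown that changes many genes, though NSL1 was measured in PGK12.1 alone. The shift was not particular to MOF siRNA. The 3 MSL1 experiments, with few changed probesets, were also all below 0 (-0.05 to -0.01), which overlaps the MOF range of -0.06 to -0.02. All 7 MOF differences within an experiment were below 0 (exact sign-flip p = 0.0156), which argues against separate scales. A dependence of X-linked genes on MOF may be the cause, as a hypothesis, but co-regulated genes could give such a shift, since camera with an estimated correlation did not call it.

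Fibroblast markers stood higher in WD44 after MOF knockdown, and residual feeder cells could be a source. Of 18 measured markers, 13 (72.2%) were higher in both experiments, but Fn1 rose by 0.15, Acta2 by 0.97, Timp3 stood at -0.12 and Thy1 at -0.02. The rise of Acta2 was not particular to WD44, since after MOF knockdown it stood at 0.55 in E14 and 0.29 in PGK12.1. The list as a whole had a median of 0.0375 in E14 and 0.02 in PGK12.1 and was called by camera in neither. Feeder cells and a change in the ES cells cannot be told apart here, because the arrays hold no separate measure of feeder cells, and depletion on gelatin would lower their share.

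Other splits of the arrays were tried for the comparisons with 3 arrays or more per group. For MOF in PGK12.1 1 of 10 splits, the real one, gave 1250 probesets, against at most 1 in the others, and 10 splits are too few for a share under 0.05. For MSL1, 6 of 56 splits gave at least the 10 real ones, so chance was not excluded. The highest other gave 4766, and it set controls C, D and E apart, which points to the structure of the sets. For arrays labelled NSL1, 9 of 56 splits gave as many as the real 4603, so chance was not excluded by this count. It is a weak test here, since the others with as many each parted at most 1 pair and followed the sets. The highest, 8061, grouped control D with knockdowns D and E. With the block, which removes the sets, 6480 changed. Among splits that part 3 pairs as the real ones do, the others gave at most 0 (3 splits, MOF), 1 (7 splits, MSL1) and 1695 (7 splits, NSL1), too few splits for a share under 0.05.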

How the results depend on the processing

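The normalization set as a block, fits within 1 set, and the block for similarity, expression level and chromosomes were chosen after seeing the data. Of 2726 values of named genes under alternatives, 2301 kept their side of the threshold, 409 kept direction but did not pass and 15 passed newly. Among values called in either fit 1 reversed (Nsl1 in arrays labelled NSL1 with array weights, -0.14). Sign changes where neither fit called the gene counted as kept, as for Kansl1 probeset 10392010 after MSL1 knockdown (0.034, or -0.032 with the block). Counts below are for MOF, MSL1, NSL1, double target, WD44 and E14 in that order unless named. With the block changed probesets were 3816 (MOF), 30 (MSL1), 1048 (double target), 2013 (WD44) and 1357 (E14), and with a random block 3675, 61, 1746 (WD44) and 1365 (E14). Array weights gave 3911, 1221, 11642, 10415, 1698 and 1418, matched controls only 2132, 0 (limma, with 1193 at an unadjusted p under 0.05), 1089, 44, 45 and 0 (with 3484), where fewer arrays enter. No filter gave 6 (MSL1), 983 (double target), 63 (WD44) and 53 (E14), a mean of at least 7 gave 189 (WD44), and cyclic loess 1995 (MOF), 16 (MSL1), 335 (WD44) and 293 (E14). A change of at least 1.5-fold left 104, 1, 802, 242, 25 and 17, and with the block 144, 1, 708, 35, 70 and 40. The set as a block gave 3152 (MOF), 745 (double target), 1266 (WD44) and 865 (E14), and MOF experiments 1 and 2 alone 395. Differences between lines were 360 (WD44 minus PGK12.1), 407 (E14 minus PGK12.1) and 226 (E14 minus WD44) with the block, and the last pair 4 and 3 without a filter. Of 132 pairs of list and comparison, camera called 28, and 4 with an estimated correlation (p53 targets in MOF, NSL1, double target and E14). With the block 15 pairs were called and by fry 13, not all of them among the 28. Among lists that camera called with or without the block, medians reversed with it for two-cell-like genes after MSL1 knockdown (0.038). After double-target knockdown they did so for the ATF4 response (-0.0035) and oxidative phosphorylation (-0.011). Lists called in neither fit reversed too, such as mesoderm genes after MSL1 knockdown (0.16 to -0.02) and endoderm genes in arrays labelled NSL1 (-0.082 to 0.031). Except where the construction shows it, the cause was not tested.

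The shift of X-linked genes was -0.025 with the block, -0.03 with matched controls and -0.028 with the set as a block for MSL1, where it passed newly. It was -0.03 (MOF) and -0.047 (double target) without a filter, and with an estimated correlation stayed -0.05 and -0.072 but did not pass. For the double target that last test cannot decide, since without the block it called 0 of 10 simulated runs at a true shift of -0.1. With the block it called 10 of 10. For arrays labelled NSL1 it reversed with cyclic loess (-0.0018) and with means (-0.0078). By expression level with the block, it was 0.001 (low), -0.036 (middle) and -0.029 (high) for MSL1, -0.052 (low) for the double target, and -0.045 (low) and -0.04 (middle) for E14. With the block 1 chromosome was called for MOF and 1 for the double target. Similarity of MSL1 with NSL1 was 0.049 with the block, -0.157 with separate and -0.09 with matched controls, that of MSL1 with the double target 0.342, 0.186 and 0.186, and that of NSL1 with the double target 0.536, 0.535 or 0.377, and 0.608. The cause was not tested.

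With 1 array left out, which leaves 1 array in some groups that is assumed to vary like the others, counts ran from 437 (without either MOF experiment 3 array) to 904 (control 1) for MOF, 1 (MSL1 array B) to 12 (control A) for MSL1, 3084 (NSL1 array E) to 7325 (NSL1 array C) for NSL1, 89 (knockdown E) to 5100 (control D) for the double target, 1 (knockdown 1) to 46 (knockdown 2) for WD44 and 6 (knockdown 2) to 173 (control 2) for E14. Differences between lines ran from 0 to 14 (WD44 minus PGK12.1), 0 to 24 (E14 minus PGK12.1) and 2 to 24 (E14 minus WD44). X-linked shifts ran from -0.061 to -0.044 (MOF), -0.041 to -0.023 (MSL1, passing without control D, -0.031, or E), 0.0048 to 0.032 (NSL1), -0.076 to -0.061 (double target), -0.045 to -0.02 (WD44) and -0.035 to -0.015 (E14), and female minus male controls from 0.51 to 0.54. Signal over background limits genes near the filter.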

Other observations

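The class test below was chosen after its first members were seen. Ttc26, Ift57 and Dync2li1 led to the hypothesis that genes of intraflagellar transport and the BBSome, which carry cargo in cilia, may fall as a group after MOF knockdown and in arrays labelled NSL1. Over the 22 other measured genes named Ift, Bbs or Dync2, the larger of the camera p-values of MOF and NSL1, with the block and an estimated correlation, was 0.00472. With the block their median was -0.22 after MOF knockdown in PGK12.1 (12 lower, 0 higher), -0.36 in arrays labelled NSL1 (17 lower, 1 higher), -0.26 in WD44 (9 lower) and -0.22 in E14 (7 lower), against 0.008 after MSL1 knockdown. After double-target knockdown, which also lowered Kat8, it was -0.11 with 1 lower (p = 0.0262 with an estimated correlation). Without the block 5 were lower there, and limma called 0 in WD44 and 0 in E14, against 10 and 8 at an unadjusted p under 0.05. Among them Bbs5 stood at -0.68 after MOF knockdown and -0.95 in arrays labelled NSL1, and Ift88 at -0.47 and -0.61. The genes were noticed and tested on the same arrays, so this stays a hypothesis.

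Y-linked genes differed between the male lines, and in E14 several stood nearer their level in female PGK12.1 than that in WD44. Kdm5d had a mean log2 value of 8.22 in WD44 and 4.29 in E14 controls (2 arrays each), Eif2s3y 10.04 and 4.58, and Zfy1 7.42 and 4.00, whereas Zfy2 was higher in E14 (5.62 against 3.62). In the PGK12.1 control groups Kdm5d stood at 4.53 and 4.42, Eif2s3y at 3.04 and 3.59, and Zfy1 at 3.51 and 3.22. Eif2s3y and Zfy1 were thus still higher in E14 than in PGK12.1. The lines were normalized apart, and the cause was not tested.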
